A study of Mus musculus with 6 samples.

How the data were processed

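RNA was profiled from CD4+ T cells of the spleen of 8-week-old C57BL/6 mice, either wild type (WT, 3 libraries) or lacking miPEP31 (miPEP31 KO, 3 libraries). The cells had been stimulated for 48 hours with antibodies against CD3 and CD28, which engage the T cell receptor complex and its costimulatory partner. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a TruSeq kit. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8 without saying in which step each was used. The counting program and its annotation are not given in the sources used here, nor is whether the counting used strand, so reads of overlapping and antisense genes cannot be told apart.

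The authors deposited a table of estimated counts per gene with 52856 rows, in which about 72% of the values above 0 were whole numbers. The deposited counts were rounded to whole numbers before testing. Of the rows, 51912 carried Ensembl gene IDs, of which 51633 had a symbol in GENCODE M21 and 279 did not. The other 944 rows had IDs starting with MSTRG and no gene name; they held between 0.903% and 1.56% of a library's counts, stayed in library sizes and tests, and are not named. Every column of per-sample values was matched to a labelled sample, so none was left out. Coordinates are those of GENCODE M21 on GRCm38, matched by gene ID and not converted from another build. The authors also deposited log10 values for 30 genes, centred per gene on 0 over the 6 libraries, and the file header states no base and no other step. The log10 scale was read from the values: their slope against centred log2 CPM (counts scaled to library size) was 0.295, where 0.301 is the log10 of 2. How these 30 genes were selected is not given in the sources used here. The tests fixed for that table assumed uncentred values, so group means and exact permutation tests were used and a pseudocount or a filter on low values could not be applied.

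Library totals ranged from 22865487 to 26295776 counts. Genes were kept with filterByExpr of edgeR 4.0.16 at its default minimum count of 10, which left 14387 rows holding 99.9% of the counts. Libraries were scaled with TMM. Groups were compared with the edgeR quasi-likelihood test with robust estimation and no covariate, and p-values were adjusted by the Benjamini-Hochberg method, with adjusted p under 0.05 as the threshold. Standard errors (SE) of log2 fold changes were taken as the unshrunk log2 fold change over the square root of the F statistic, and none is given where a group had no count. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, or for sums of such genes, the ratio has an exact 95% counting interval. Floors and intervals cover counting error only. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were also used.

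The gene lists (T cell programmes, cell cycle, metabolism, stress and signalling responses, reported miR-31 targets, and markers of other cell types) and the symbol classes were written from general knowledge before the data were examined, as were the design, most alternatives and the rule for the genes named. That rule took any Mir31 row first. It then took the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out gene models without a proper name, pseudogenes and immune receptor variable segments. From each list it took up to 4 members past the threshold by smallest p, or the 2 with the smallest p where none passed, and for lists of other cell types also the 2 most abundant members. Foxp3, Il2ra, Ctla4, Tbx21, Ifng, Gata3, Il4, Il17a, Il10, Il2 and Cd4 were taken whatever their test. Some genes that the rule takes are not reported here. Lists of at least 3 tested members were tested with camera of limma at a preset correlation of 0.01, which compares a list with all other genes, and alternatively with an estimated correlation and with fry. Shares of counts were compared with two-sided exact permutation tests, for which 3 against 3 libraries allow no p below 0.1.

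Matches to the seed of miR-31-5p (TCTTGCC, opposite its positions 2 to 8) were searched in the longest annotated 3' UTR of 21150 genes. Fold changes of genes with a match were compared with 10000 random sets of genes without one, matched on 3' UTR length and mean expression. Genes with no annotated 3' UTR counted as not searched.

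The scripts were tested on data simulated from the real means and library sizes for miPEP31 KO against WT, with 14387 genes. The edgeR test recovered 44% of 50 genes changed 1.5-fold, 76% at 2-fold, 100% at 4-fold and 100% at 8-fold, and 9.09% of its 176 calls were unchanged genes. The corresponding share was 17.8% of 208 calls for DESeq2 and 7.43% of 175 for limma-voom. Camera found the 1 list that had been shifted and called 0 of the others. The seed match test called 5 of 50 simulations without an effect and 50 of 50 with a shift of -0.1 on the log2 scale. Alternatives were RLE and upper-quartile scaling, plain library sizes, other low-count filters, DESeq2, limma-voom, a replicate block, stricter thresholds, immune receptor segments left out, and each library left out in turn.

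No pair of libraries held identical values. Between replicates, the chi-square statistic per gene was 5.08 to 8.34 for the WT pairs and 14.6 to 39.7 for the KO pairs, where sampling noise alone gives about 1. The labels do not say that the replicates came from separate mice, and p-values then measure only the spread between these samples, which may be technical.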

Results

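miPEP31 is a peptide encoded by the primary transcript of the microRNA miR-31. The comparison asks how its loss changes the transcriptome of CD4+ T cells, the helper and regulatory T cells, 48 hours after stimulation through CD3 and CD28. Gene expression was measured by RNA-seq in 3 WT and 3 miPEP31 KO libraries. Total counts were 23474669, 24018687 and 23398486 in the WT libraries and 23046153, 26295776 and 22865487 in the KO libraries. The targeted locus was looked at first. Mir31 (ENSMUSG00000065408, chromosome 4, 88910557 to 88910662, GRCm38, annotated as a miRNA gene) had 0 counts in all 6 libraries, so these counts do not check the genotype labels.

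Loss of miPEP31 went with broad changes. Of 14387 genes tested, 6806 differed between the groups (edgeR quasi-likelihood test, adjusted p under 0.05), 3609 higher and 3197 lower in the KO. Of these, 970 were higher and 1017 lower by at least 2-fold. In 8496 of the 14387 tested genes the 3 KO libraries did not overlap the 3 WT libraries, which chance gives for 10% of genes. The first principal component separated the genotypes and held 74.9% of the variance. The second held 10.4% and spread the KO libraries, from 31.8 in KO replicate 1 to -35.5 in KO replicate 3, with the WT libraries between 1.22 and 3.92.

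Interferon-response genes rose the most. All 34 members of the type I interferon list were higher in the KO, with a median log2 fold change of 3.90, which was the same with Ifit3b at its lower bound, and all 34 passed when adjusted over the list alone. The list test gave a camera adjusted p = 2.04e-20, and an adjusted p = 0.608 with an estimated correlation. Irf7, the transcription factor that amplifies interferon production, rose from a mean of 1.99 CPM in WT to 159 CPM in KO, a log2 fold change of 6.31 (SE 0.19, edgeR adjusted p = 1.24e-06). Xaf1, a pro-apoptotic interferon-induced gene, rose by 5.98 (SE 0.18), Ifi27l2a by 2.76 (SE 0.08) and Irf9, a subunit of the transcription factor ISGF3, by 2.06 (SE 0.07). Of the 8 largest rises in the data, 6 had counts in both groups. Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960) went from 0.0868 ± 0.0867 to 74.0 ± 33.9 CPM, Rtp4 from 0.0994 ± 0.106 to 19.9 ± 6.11, Ifi206 from 0.287 ± 0.0292 to 39.4 ± 17.8 and Ifi214 from 0.0576 ± 0.0666 to 8.07 ± 3.01 (SD, n = 3 each). Mx1, which encodes an antiviral GTPase, went from 1.06 ± 0.438 to 125 ± 61.8 CPM, and Rsad2, which encodes viperin, from 0.732 ± 0.154 to 76.9 ± 30.1. The log2 fold changes of Ifi44, Rtp4 and Ifi214 were 9.66, 7.56 and 7.01, and 10.59 without WT replicate 1, 8.67 without WT replicate 2 and 8.24 without WT replicate 3, respectively. The other 2 had no WT count. The interferon gene Ifna2 was at least 55.0-fold higher in KO, with 117, 38 and 13 counts in its libraries, and Ifit3b at least 54.3-fold higher, with 94, 60 and 12 counts. Without KO replicate 1 these bounds were 24.5-fold and 34.6-fold. Both lost their call without the low-count filter (edgeR adjusted p = 0.168 and 0.0877). Ifna2, Ifit3b, Ifi206 and Ifi214 have close paralogs with which reads can be shared, so their levels are uncertain.

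**Figure D1:**
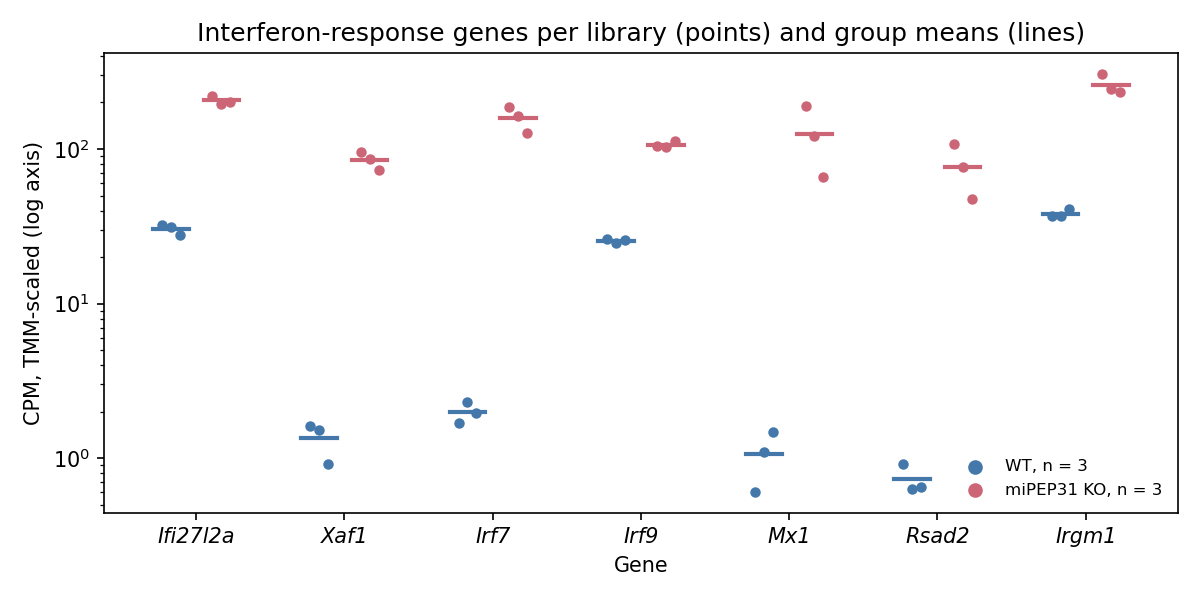
CPM (log axis) of 7 interferon-response genes in each library; points are libraries, lines are group means (n = 3 per group). For each of the 7 genes all KO libraries lie above all WT libraries, as for Irf7 at 159 CPM in KO against 1.99 in WT.

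The interferon-gamma list followed, with 22 of 23 members higher, 1 lower and a median log2 fold change of 1.26 (camera adjusted p = 2.21e-09, adjusted p = 0.608 with an estimated correlation). Adjusted over the list alone, the counts were also 22 and 1. The GTPase genes Irgm1, Gbp6 and Gbp4 rose by 2.77 (SE 0.11), 2.80 (SE 0.12) and 1.49 (SE 0.06) on the log2 scale. Gbp4 and Gbp6 belong to a family of close paralogs. Ifng itself had 76.1 ± 24.6 CPM in WT and 99.6 ± 65.1 in KO and did not pass the test (log2 fold change 0.39, edgeR adjusted p = 0.516). Without KO replicate 1 its log2 fold change was -0.22. The KO libraries differed from each other: relative to the WT mean, the median of the type I list was 4.19, 3.80 and 3.28 in KO replicates 1, 2 and 3, while the WT libraries lay between -0.01 and 0.03. Summed markers of macrophages (74.7 to 164 CPM) and of dendritic cells (101 to 178 CPM) also stood higher in the KO (exact permutation p = 0.1 each, the smallest possible). Few members carried these sums: without Batf3 the dendritic cell markers went from 82.4 to 72.5 CPM, and without Mpeg1, Ctss, Hmox1 and Cybb the macrophage markers went from 17.1 to 15.9 CPM. These 5 genes were chosen after their values were seen.

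Genes of the integrated stress and unfolded protein responses rose as well. Of 28 tested, 24 were higher, 1 lower and 3 did not pass, with a median of 0.66 (camera adjusted p = 1.28e-07, adjusted p = 0.608 with an estimated correlation), and adjusted over the list alone 24 were higher and 1 lower. Atf3, a stress-induced transcription factor, rose by 1.63 (SE 0.10), Chac1, a glutathione-degrading enzyme, by 1.83 (SE 0.14), Creld2 by 1.15 (SE 0.08) and the amino acid transporter subunit Slc3a2 by 0.83 (SE 0.07). Among NF-kB targets 12 of 20 were higher and 3 lower, or 13 and 3 adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.0382, adjusted p = 0.609 with an estimated correlation). Relb, Icam1 and Nfkbie rose by 0.61 (SE 0.07), 0.74 (SE 0.08) and 0.73 (SE 0.09), and Ltb, which encodes lymphotoxin beta, fell by 1.15 (SE 0.06). Without WT replicate 1, 2 or 3 only 1 member of this list was lower. Its camera adjusted p was 0.0570 without WT replicate 2 and 0.0649 without WT replicate 3.

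**Figure D2:**
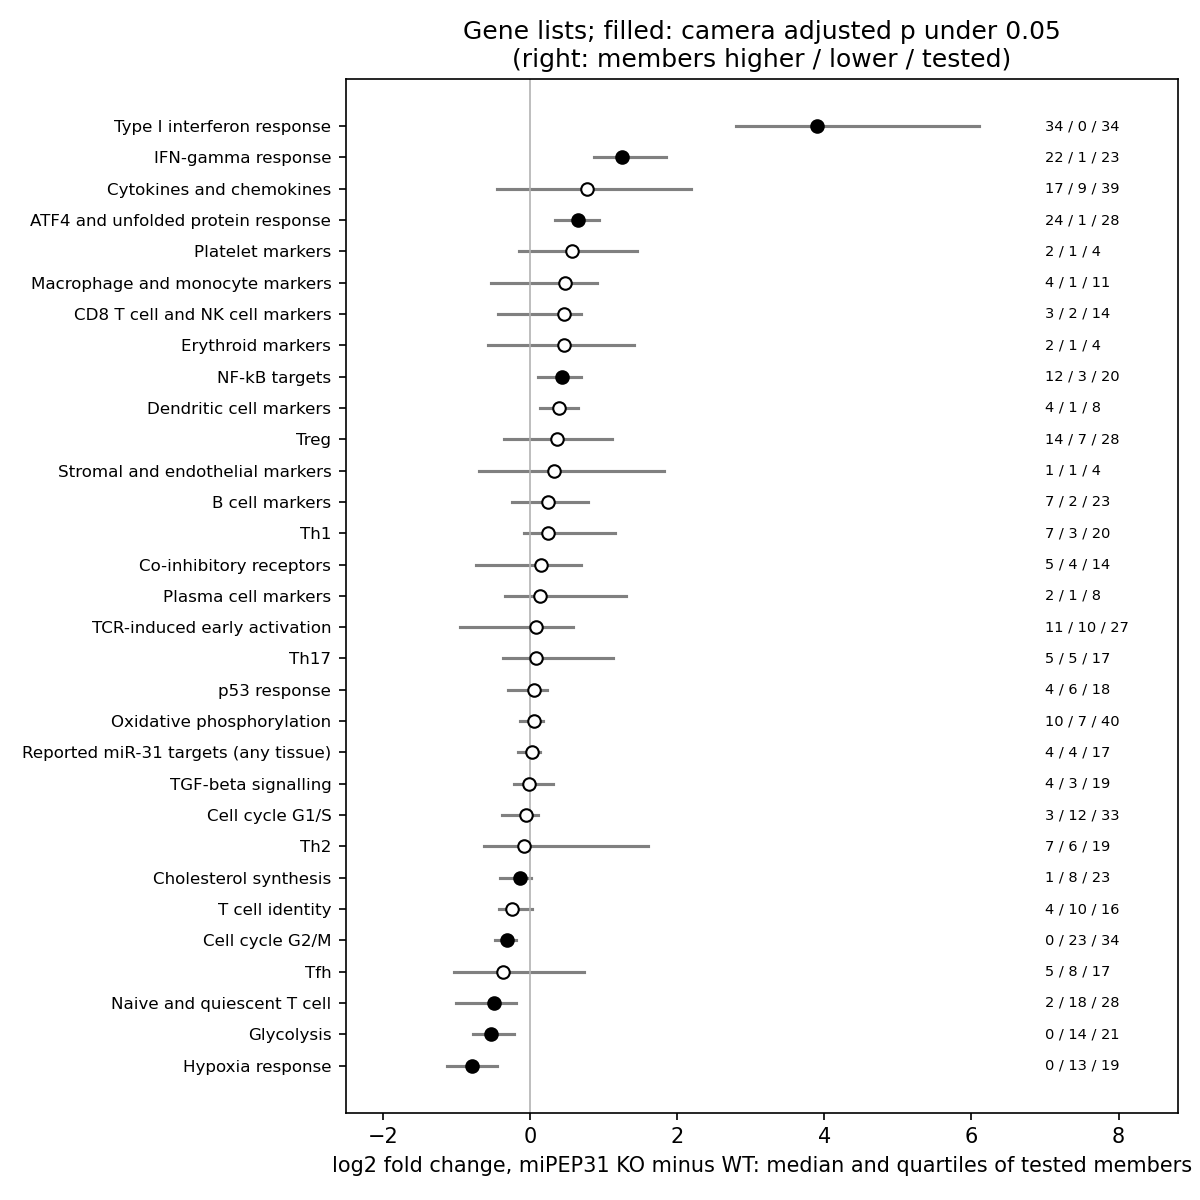
Median and quartiles of the log2 fold change (miPEP31 KO minus WT) for 31 gene lists; filled points have a camera adjusted p under 0.05 at the preset correlation, and the numbers give members higher, lower and tested. The type I interferon list stands farthest out, at 3.90 with 34 of 34 members higher.

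Several cytokine genes were strongly higher. Of 39 tested cytokine and chemokine genes, 17 were higher, 9 lower and 13 did not pass, with a median of 0.78; adjusted over the list alone the counts were 17 and 10 (camera adjusted p = 0.220), and without KO replicate 1 the median was 0.40. Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), a chemokine for effector T cells and monocytes, rose 27.3-fold, from 5.02 ± 0.331 to 137 ± 8.92 CPM (SD, n = 3, edgeR adjusted p = 1.91e-07). Il6 rose from 0.359 ± 0.102 to 20.4 ± 4.95 CPM. Tnfsf14 fell by 1.85 (SE 0.09).

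Individual genes of the helper T cell lineages rose or fell, while none of the Th1, Th2 and Th17 lists passed camera. In the Th1 list 7 of 20 were higher and 3 lower (median 0.24, camera adjusted p = 0.168), with the same counts adjusted over the list alone. Tbx21, the Th1 master transcription factor, rose 2.01-fold (log2 fold change 1.01, WT 48.5 ± 6.53 CPM, SD, n = 3), Ccl4 rose by 2.77 (SE 0.17) and Hopx by 1.05 (SE 0.09). In the Th2 list 7 of 19 were higher and 6 lower, or 7 and 7 adjusted over the list alone (median -0.09, mean 0.32, camera direction down, adjusted p = 0.987). Il13 and Il4, the cytokines of Th2 cells, rose 9.28-fold and 3.58-fold, whereas their transcription factor Gata3 fell by 0.57 (SE 0.14), Stat6 by 0.38 (SE 0.05), and the chemokine receptors Ccr8 by 1.83 (SE 0.10) and Ccr4 by 0.75 (SE 0.11). In the Th17 list 5 of 17 were higher and 5 lower, also adjusted over the list alone (median 0.08, camera adjusted p = 0.924). Members higher were 3 without WT replicate 1 or 2, and members lower were 3 without WT replicate 3 or KO replicate 2. Il22 rose from 2.41 ± 0.256 to 23.2 ± 17.5 CPM and Csf2, the gene of GM-CSF, from 7.97 ± 2.38 to 42.1 ± 24.2, and Il6ra and Basp1 were lower by log2 fold changes of -1.40 (SE 0.14) and -1.33 (SE 0.21). The log2 fold change of Il22 was 3.27, and 2.47 without KO replicate 3. The Csf2 call was lost without the low-count filter (edgeR adjusted p = 0.0502). Il17a had 0.951 ± 0.407 and 1.64 ± 1.93 CPM and did not pass (log2 fold change 0.78, edgeR adjusted p = 0.452). Without KO replicate 3 its log2 fold change was -0.83.

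Regulatory T cell genes went both ways. Of 28, 14 were higher, 7 lower and 7 did not pass, or 15 and 8 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.189). Without WT replicate 1 only 4 were lower. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), which specifies regulatory T cells, rose 3.69-fold, from 8.78 ± 1.38 to 32.4 ± 7.40 CPM (SD, n = 3), a log2 fold change of 1.89 (SE 0.19, edgeR adjusted p = 1.77e-04). Il10, an inhibitory cytokine, rose by 2.34 (SE 0.41), Penk by 1.89 (SE 0.17) and the phosphatase gene Dusp4 by 1.00 (SE 0.09), and Izumo1r, the gene of folate receptor 4, fell by 1.19 (SE 0.08). Il2ra, the gene of CD25, had 2271 ± 72.6 CPM in WT and 2898 ± 519 in KO (log2 fold change 0.35, SE 0.12, edgeR adjusted p = 0.0391). Its call was lost without WT replicate 1, 2 or 3 or KO replicate 2 or 3 (edgeR adjusted p 0.0934 to 0.131), with upper-quartile scaling (adjusted p = 0.0780) and without the low-count filter (adjusted p = 0.0844), and its log2 fold change was 0.21 without KO replicate 3. Ctla4 had 531 ± 53.2 and 378 ± 181 CPM and did not pass (edgeR adjusted p = 0.196). Without KO replicate 3 its log2 fold change was -0.94 with an edgeR adjusted p of 0.00838. In the follicular helper list 5 of 17 were higher and 8 lower, also adjusted over the list alone (median -0.36, camera adjusted p = 0.220), with falls of Btla by 1.16 (SE 0.07), Sh2d1a by 1.32 (SE 0.13), Cd40lg by 1.30 (SE 0.14) and Tcf7 by 0.95 (SE 0.13). Among co-inhibitory receptors 5 of 14 were higher and 4 lower, also adjusted over the list alone (median 0.15, mean -0.11, camera direction down, adjusted p = 0.870), with Vsir, the gene of VISTA, lower by a log2 fold change of -2.18 (SE 0.08), Lag3 lower at -0.82 (SE 0.09) and Pdcd1lg2 higher at 0.58 (SE 0.06).

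**Figure D3:**
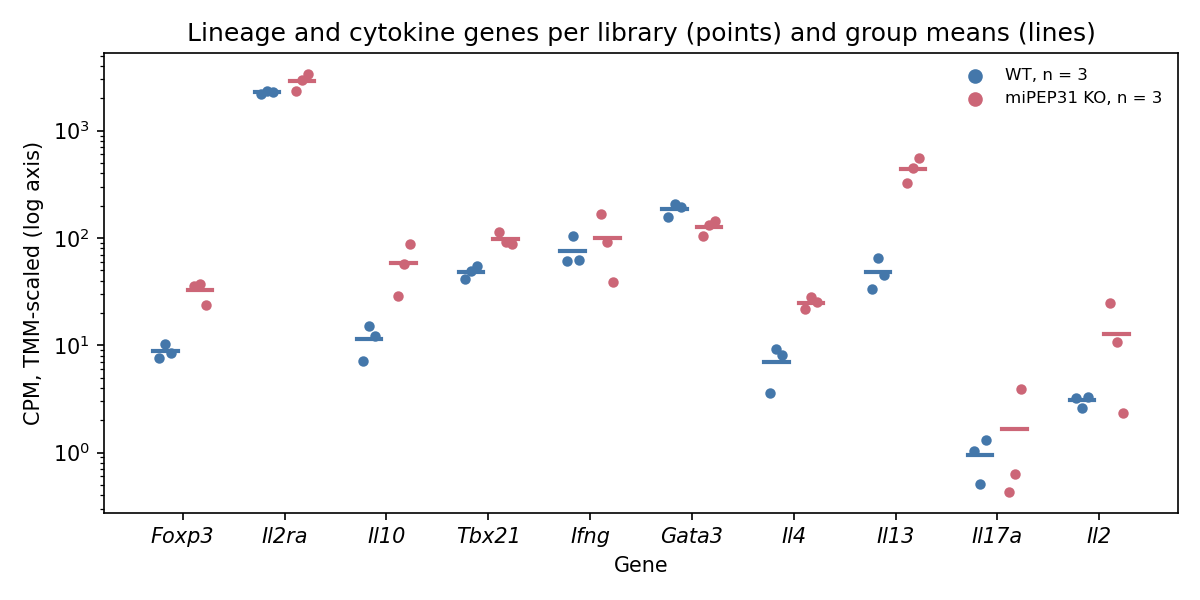
CPM (log axis) of 10 lineage and cytokine genes in each library; points are libraries, lines are group means (n = 3 per group). Foxp3 and Il13 separate the groups, while the KO libraries of Ifng, Il17a and Il2 are widely spread.

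Genes of naive and quiescent T cells fell. Of 28, 18 were lower, 2 higher and 8 did not pass, with a median of -0.48 and the same counts adjusted over the list alone (camera adjusted p = 2.27e-04, adjusted p = 0.608 with an estimated correlation). Without KO replicate 1, 5 were higher. Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392), a binding protein of insulin-like growth factors, was 13.7-fold lower, at 158 ± 11.4 CPM in WT and 11.6 ± 1.13 in KO (SD, n = 3, edgeR adjusted p = 6.28e-07). The transcription factors Bach2 and Lef1 fell by 1.15 (SE 0.08) and 0.68 (SE 0.05). Of 16 T cell identity genes 10 were lower and 4 higher, also adjusted over the list alone (median -0.24, camera adjusted p = 0.111). Only 2 were higher without WT replicate 1, 2 or 3 or KO replicate 2. Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221) went from 456 ± 38.6 to 302 ± 7.87 CPM. Trac fell by 0.53 (SE 0.05) and the kinase gene Zap70 by 1.08 (SE 0.08), and Cd5, an inhibitory receptor, rose by 0.73 (SE 0.06). Genes induced early by the T cell receptor went both ways, 11 of 27 higher and 10 lower, or 12 and 12 adjusted over the list alone (median 0.08, mean 0.01, camera direction down, adjusted p = 0.987). Egr1 rose by 1.86 (SE 0.16), Dusp2 by 1.15 (SE 0.10), Junb by 0.68 (SE 0.07) and Tnfrsf4, the gene of OX40, by 0.55 (SE 0.05). Il2 stood at 3.06 ± 0.382 CPM in WT and 12.7 ± 11.5 in KO (log2 fold change 2.05, SE 0.69, edgeR adjusted p = 0.0395). Its call was lost without any 1 of the WT libraries or KO replicate 1 or 2 (edgeR adjusted p 0.0853 to 0.198), without KO replicate 1 the log2 fold change was 1.10, and the call was also lost with limma-voom (adjusted p = 0.212). In edgeR it was lost with a replicate block (adjusted p = 0.0796), upper-quartile scaling (adjusted p = 0.060), no low-count filter (adjusted p = 0.232) and a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0527).

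The largest falls were in genes of varied function. Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525), the template-independent polymerase of antigen receptor rearrangement, was 114-fold lower, at 28.7 ± 4.91 CPM in WT and 0.249 ± 0.160 in KO (SD, n = 3). Endou went from 11.7 ± 1.87 to 0.185 ± 0.0973 CPM, the growth factor gene Tgfb3 from 74.3 ± 9.13 to 2.25 ± 1.53, and Acvrl1, a receptor of the TGF-beta family, from 54.7 ± 9.05 to 1.95 ± 0.919. Slc38a3, Nags and Stc1 had log2 fold changes of -4.91 (SE 0.32), -4.98 (SE 0.55) and -4.82 (SE 0.59). Without KO replicate 3, Nags and Stc1 stood at -5.69 and -5.71, Dntt at -7.46 against -6.84 with all libraries, and Tgfb3 at -5.63 against -5.04. Of 19 TGF-beta signalling genes, 4 were higher and 3 lower, also adjusted over the list alone (median -0.02, camera direction up, adjusted p = 0.870): beside Tgfb3, Pmepa1 rose by 1.19 (SE 0.11), Itgav by 0.77 (SE 0.08) and Skil by 0.64 (SE 0.06).

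Glycolysis, hypoxia and mitosis genes were lower. Of 21 glycolysis genes 14 were lower and 0 higher, or 15 and 0 adjusted over the list alone (median -0.53, camera adjusted p = 1.33e-04, adjusted p = 0.724 with an estimated correlation). Slc2a3, a glucose transporter, was 7.59-fold lower, at 1574 ± 210 CPM in WT and 207 ± 122 in KO (SD, n = 3), Eno3 fell by 1.72 (SE 0.13), Gpi1 by 0.83 (SE 0.11) and Pfkfb3 by 0.81 (SE 0.06). Of 19 hypoxia-response genes 13 were lower and 0 higher, also adjusted over the list alone (median -0.79, camera adjusted p = 1.62e-04, adjusted p = 0.743 with an estimated correlation), with Ndrg1 lower by a log2 fold change of -1.82 (SE 0.27), Ankrd37 at -1.21 (SE 0.19), Pdk1 at -1.04 (SE 0.12) and Kdm3a at -0.45 (SE 0.08). Of 34 G2/M genes 23 were lower and 0 higher, or 24 and 0 adjusted over the list alone (median -0.31, camera adjusted p = 2.42e-06, adjusted p = 0.609 with an estimated correlation). The mitotic kinase genes Ttk and Aurkb fell by 1.10 (SE 0.06) and 0.60 (SE 0.06), Cenpa by 0.70 (SE 0.07) and Ccnb2 by 0.63 (SE 0.07). Of 33 G1/S genes 12 were lower and 3 higher, also adjusted over the list alone (median -0.06, camera adjusted p = 0.189). The list was called lower without KO replicate 1 (camera adjusted p = 0.0231). E2f2, Cdt1 and Mcm7 fell by 0.50 (SE 0.06), 0.53 (SE 0.08) and 0.52 (SE 0.08), and Ccne1 rose by 0.78 (SE 0.09). Cholesterol synthesis genes were lower in 8 of 23 and higher in 1, also adjusted over the list alone (median -0.14, camera adjusted p = 0.0480, adjusted p = 0.724 with an estimated correlation). Stard4, Lss, Acat2 and Nsdhl fell by 0.90 (SE 0.07), 0.60 (SE 0.08), 0.43 (SE 0.07) and 0.46 (SE 0.08). That list's call was lost with a replicate block (camera adjusted p = 0.0790), with plain library sizes (camera adjusted p = 0.0881), and without WT replicate 1 or 3 or KO replicate 2 or 3 (camera adjusted p 0.0503 to 0.128).

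The oxidative phosphorylation and p53 lists did not pass camera. Oxidative phosphorylation genes were higher in 10 of 40 and lower in 7, or 9 and 7 adjusted over the list alone (median 0.05, camera adjusted p = 0.870), with Uqcrq, Ndufb10 and Ndufa2 higher at 0.51 (SE 0.07), 0.37 (SE 0.07) and 0.39 (SE 0.08) and Sdhd lower at -0.31 (SE 0.07). These counts were 5 and 4 without WT replicate 1 or 3, 4 and 2 without WT replicate 2, and 5 and 3 without KO replicate 2. Of 18 p53-response genes 4 were higher and 6 lower, also adjusted over the list alone (median 0.06, camera adjusted p = 0.987). Only 3 were lower without WT replicate 2 or 3, and 2 without KO replicate 2. The death genes Pmaip1 and Fas rose by 1.76 (SE 0.08) and 1.12 (SE 0.13), and Trp53inp1 and Zmat3 fell by 0.76 (SE 0.11) and 0.71 (SE 0.12).

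Signal of other cell types was small in both groups. B cell markers took 0.0588% ± 0.00703 of counts in WT and 0.0824% ± 0.0309 in KO (SD, n = 3, exact permutation p = 0.3), and 7 of 23 were higher and 2 lower, or 4 and 1 adjusted over the list alone (median 0.24, camera adjusted p = 0.567). Members higher were 4 without WT replicate 1 or 2 or KO replicate 2 or 3. Members lower were 1 without any 1 WT library, 0 without KO replicate 2 and 4 without KO replicate 3. Cd74, the invariant chain, went from 96.0 ± 16.2 to 205 ± 66.7 CPM, Ms4a1 rose by 0.92 (SE 0.17), Igkc by 1.30 (SE 0.31), and Fcer2a fell by 0.97 (SE 0.24), while Ighm had 137 ± 21.4 and 230 ± 105 CPM and did not pass (edgeR adjusted p = 0.0614, and 0.0333 with a replicate block). Without the low-count filter the calls of Cd74 and Igkc were lost (edgeR adjusted p = 0.0733 and 0.111), and Igkc lost its call without WT replicate 1 (edgeR adjusted p = 0.0572) and Fcer2a without KO replicate 2 (edgeR adjusted p = 0.0536). Plasma cell markers had 2 of 8 higher and 1 lower, also adjusted over the list alone (median 0.13, camera adjusted p = 0.878). Without KO replicate 1, 4 were higher, and 0 were lower without WT replicate 3 or KO replicate 2. Igha rose from 0.101 ± 0.140 to 1.69 ± 0.548 CPM (log2 fold change 5.99 without WT replicate 1) and Ighg1 fell by 1.45 (SE 0.36), a call lost without WT replicate 3 or KO replicate 2 (edgeR adjusted p = 0.0584 and 0.0589) and without the low-count filter (adjusted p = 0.115). Of 14 CD8 T cell and NK cell markers 3 were higher and 2 lower, also adjusted over the list alone (median 0.46, camera adjusted p = 0.870). Without KO replicate 1, 5 were higher, and without KO replicate 3 the median was 0.17. Cd8a rose from 3.29 ± 1.02 to 12.2 ± 4.68 CPM, Klrk1 by 0.90 (SE 0.15) and Eomes by 1.54 (SE 0.29). Nkg7 fell by 0.94 (SE 0.11), and Gzma had 65.8 ± 21.3 and 107 ± 55.0 CPM (edgeR adjusted p = 0.143). Of 11 macrophage markers 4 were higher and 1 lower, also adjusted over the list alone (median 0.48, camera adjusted p = 0.384). The median was 0.13 without KO replicate 3 and 0.29 without WT replicate 3. Mpeg1 went from 1.25 ± 0.431 to 42.8 ± 17.9 CPM, Cybb rose by 1.81 (SE 0.18), Ctss by 0.72 (SE 0.10) and Hmox1 by 0.74 (SE 0.11). Of 8 dendritic cell markers 4 were higher and 1 lower, also adjusted over the list alone (median 0.40, camera adjusted p = 0.290): Batf3, which activated T cells also express, rose by 2.46 (SE 0.11), Zbtb46 by 1.05 (SE 0.24) and Fscn1 by 0.32 (SE 0.09), and Ccl22 fell by 1.00 (SE 0.17). Only 2 dendritic cell markers were higher without WT replicate 1 or 2 or KO replicate 2 or 3, and without KO replicate 3 the median was 0.18. The Fscn1 call was lost without WT replicate 1 or 2 or KO replicate 2 or 3 (edgeR adjusted p 0.0587 to 0.0850), without the low-count filter (adjusted p = 0.0594) and with a replicate block (adjusted p = 0.0532). Of 2 neutrophil and mast cell markers tested, Cxcr2 fell by 3.57 (SE 0.52) and Gata2 rose by 1.92 (SE 0.41). Without KO replicate 3 the log2 fold change of Cxcr2 was -4.38. Of 4 erythroid markers 2 were higher and 1 lower (Car2 1.29, Car1 1.78 and Hemgn -1.18 on the log2 scale), of 4 platelet markers 2 were higher and 1 lower (Pf4 2.48, Itga2b 1.12 and Itgb3 -0.69), and of 4 stromal markers 1 was higher and 1 lower (Lum 3.90 and Pecam1 -1.27); adjusted over the list alone these counts were the same except for 2 stromal markers higher. The camera adjusted p was 0.870 for the erythroid list (median 0.46), 0.749 for the platelet list (median 0.58) and 0.987 for the stromal list (median 0.32, camera direction down). Itga2b lost its call without WT replicate 1 or 3 or KO replicate 2 (edgeR adjusted p 0.0536 to 0.0618), and Lum without the low-count filter (edgeR adjusted p = 0.0792). The log2 fold change of Lum was 4.61 without WT replicate 1 and 2.88 without KO replicate 3.

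Cytosolic ribosomal protein genes took 8.22% ± 0.0428 of counts in WT and 7.62% ± 0.243 in KO, and mitochondrially encoded genes 2.06% ± 0.0554 and 1.72% ± 0.0738 (SD, n = 3, exact permutation p = 0.1 each). Histone genes took 0.00502% ± 0.000541 and 0.00598% ± 0.000571 and immunoglobulin segments 0.0235% ± 0.00392 and 0.0369% ± 0.0164 (exact permutation p = 0.2 each), and T cell receptor variable segments 0.0153% ± 0.000995 and 0.0128% ± 0.000505 (exact permutation p = 0.1). As sets, ribosomal protein genes (camera adjusted p = 6.09e-05, adjusted p = 0.637 with an estimated correlation) and T cell receptor segments (camera adjusted p = 0.00251, adjusted p = 0.362 with an estimated correlation) were called lower. Immunoglobulin segments were called higher (camera adjusted p = 0.0185, adjusted p = 0.637 with an estimated correlation). Mitochondrially encoded genes (camera adjusted p = 0.491) and histone genes (camera adjusted p = 0.261) did not pass as sets.

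**Figure D4:**
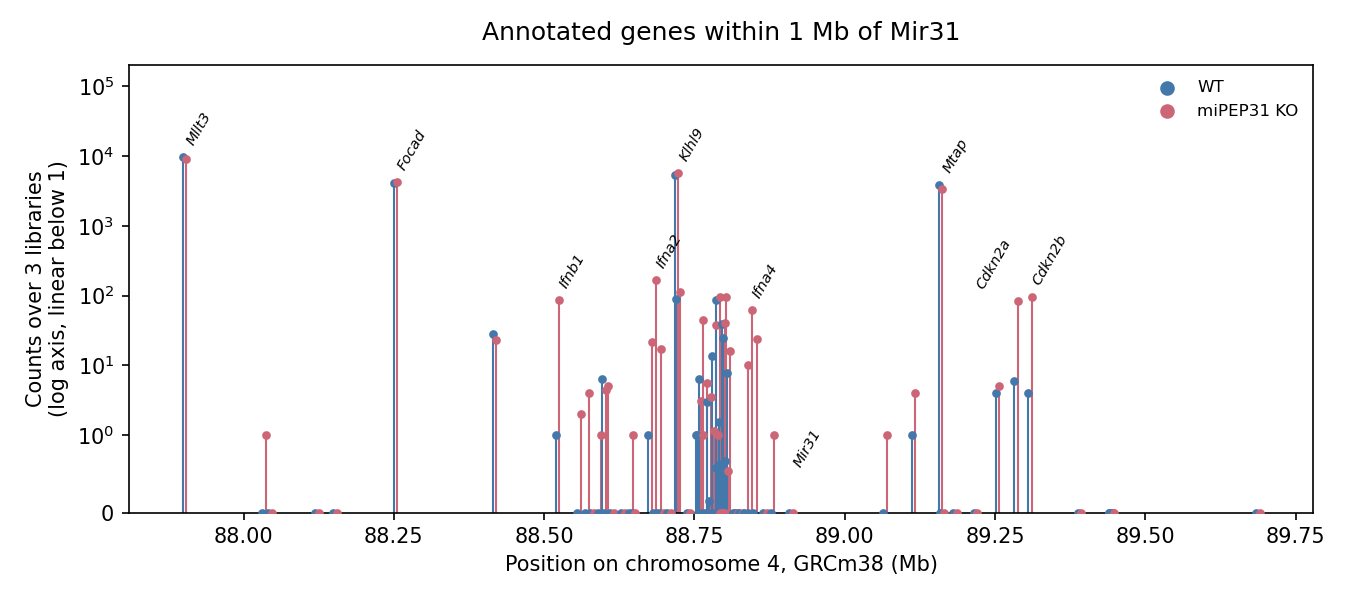
Counts summed over 3 libraries per group (log axis, linear below 1) for annotated genes within 1 Mb of Mir31 on chromosome 4 of GRCm38. Ifna2 has 168 counts in KO and 0 in WT, and Mir31 has 0 in both.

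Because the peptide comes from the transcript that carries miR-31, transcripts with a seed match to this microRNA were compared with the rest. Of 12079 tested genes with a searched 3' UTR, 1647 held the 7-base match TCTTGCC and 10432 did not. Their median log2 fold changes were 0.03 and 0.04. Against 10000 matched random sets, whose medians averaged 0.04 with 95% of them between 0.01 and 0.07, the genes with a match differed by -0.0046 (p = 0.736, two-sided permutation test over the random sets). Of the genes with a match 28.6% were higher and 23.7% lower, compared with 27.5% and 21.8% of the others. In the list of reported miR-31 targets 4 of 17 tested genes were higher and 4 lower, also adjusted over the list alone (median 0.03, mean -0.04, camera direction down, adjusted p = 0.998): Rasa1, Stk40 and Hif1an rose by 0.60 (SE 0.07), 0.58 (SE 0.08) and 0.28 (SE 0.06), and Nfat5 fell by 0.60 (SE 0.08). Only 2 of the list were lower without WT replicate 1 or 2 or KO replicate 2.

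The small table the authors deposited holds 30 genes, and 29 of them had lower centred log10 values in the KO. The KO libraries lay below the WT libraries without overlap in 22, where chance gives 10% of genes in either direction (exact permutation p = 0.1 for each, the smallest possible). All 30 had the same direction in the count table, where 22 were called lower and 0 higher (edgeR; 8 did not pass). How these genes were selected is not given in the sources used here, so neither their direction nor their seed matches are taken as independent evidence. The following genes were chosen after their values were seen. Myo6 had the largest difference, -1.20 (log10), and fell by 2.78 on the log2 scale (SE 0.26) in the count table, a smaller fold. Specc1 differed by -0.189 (log10), again with the smaller fold in the count table (log2 fold change -0.10, SE 0.19, edgeR adjusted p = 0.673). Soat1 differed by -0.111 (log10), with the larger fold in the count table (log2 fold change -0.85, SE 0.11). The 2 tables thus shared direction but not always size. Gprc5a differed by -0.0913 (exact permutation p = 0.2; count table -0.47, SE 0.24, edgeR adjusted p = 0.134), and Ppp2r2a by -0.0327 (exact permutation p = 0.2; count table -0.15, SE 0.07, edgeR adjusted p = 0.0981). The next comparison was added after the data were seen. Of the 30 genes, 15 held the 7-base seed match, or 50%, against 13.5% of the 12049 other tested genes searched. Random sets matched on 3' UTR length held 5.58 such genes on average, with 95% of the sets between 2 and 10. A selection of predicted miR-31 targets would give such a share by itself, so no p is given.

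**Figure D5:**
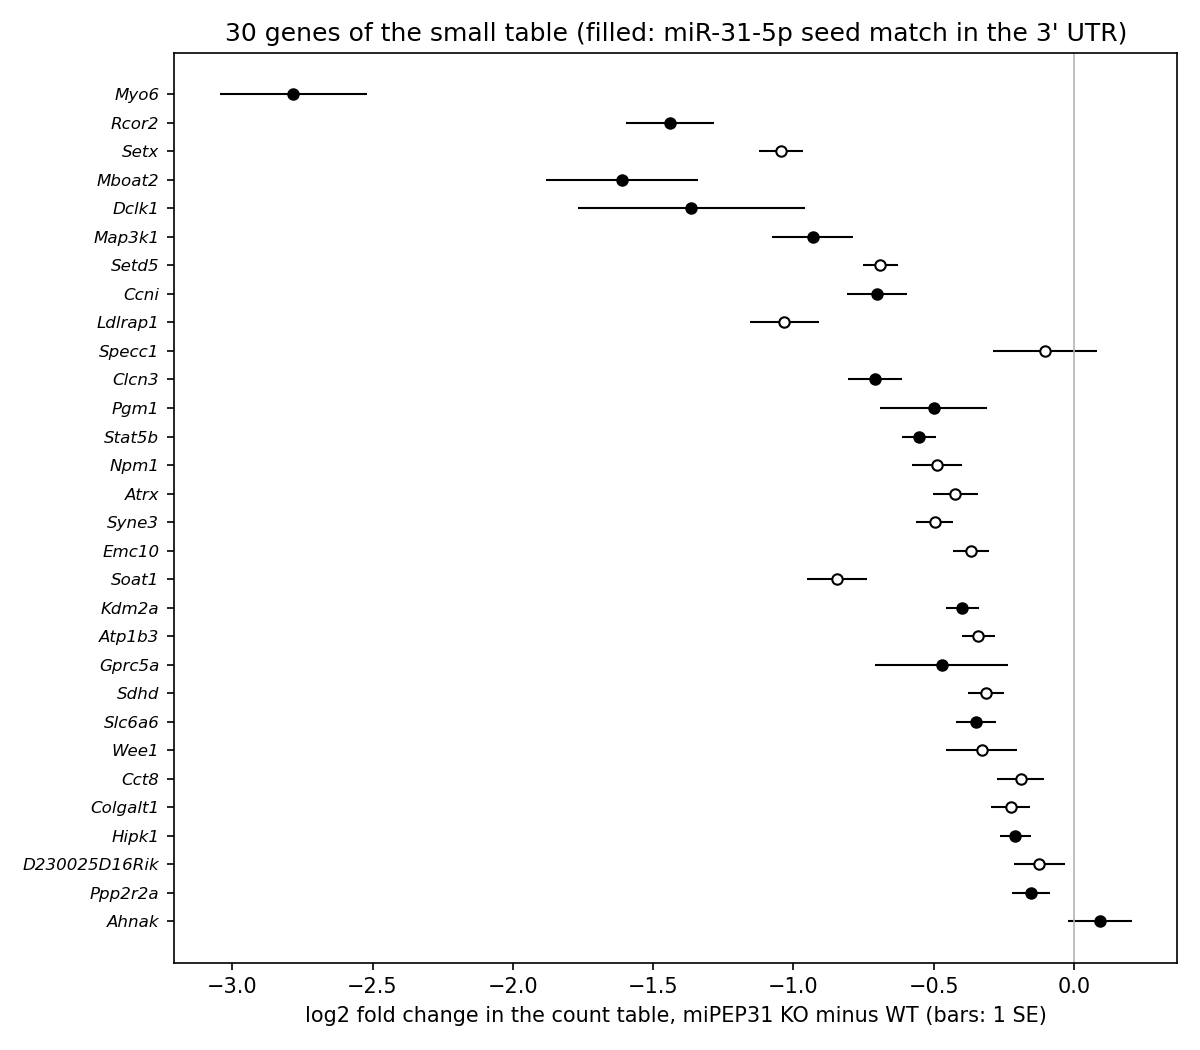
Log2 fold change in the count table (miPEP31 KO minus WT, bars 1 SE) of the 30 genes of the small table; filled points have a miR-31-5p seed match in the 3' UTR. All but Ahnak lie below 0, and 15 of the 30 are filled.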

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

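The tests on the interferon and naive-cell patterns, but not the splits of the libraries, were chosen after the results were seen. Interferon genes that the low-count filter kept out of the tests still held counts in the KO libraries, and this signal outside the main comparison is why they are given. The 18 such genes summed to 371 counts in KO and 15.7 in WT, a ratio of 23.3 with a 95% counting interval from 13.8 to 40.2. By library the sums were 222, 106 and 42.7 in KO and 2.37, 9.03 and 4.26 in WT, and the ratio was 13.7 without KO replicate 1 and 36.3 without WT replicate 2. The genes named here were chosen after their values were seen. Ifnb1 had 52, 26 and 9 counts in KO replicates 1, 2 and 3 and 1 in the 3 WT libraries together. Ifna4 had 36, 19 and 8 counts in KO and 0 in WT, at least 20.6-fold higher against a floor of 3 counts over the group, and Ifnl3 had 57.2, 34 and 5.47 in KO and 0 in WT, at least 31.6-fold higher; without KO replicate 1 these bounds were 13-fold and 19-fold. Reads can be shared among the interferon alpha genes and between Ifnl2 and Ifnl3. Ifnz, also on chromosome 4, held most of the WT counts, with 2.37, 7.03 and 4.26 in WT and 14.1, 8.99 and 14.3 in KO. Summed over the 17 other chromosome 4 genes with the name of a type I interferon, the KO libraries held 268, 101 and 36 counts. The WT libraries held 0, 2 and 0. The interferon lambda genes on chromosome 7 held 198, 129 and 26 in KO and 0, 0 and 2 in WT.

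For the rise of interferon-response genes, RNA of macrophages, dendritic cells or B cells was weighed first. Summed over the 3 marker lists, their CPM rose by a log2 ratio of 0.61, from 764 to 1167 CPM. The type I interferon list rose from 500.5 to 4568 CPM. The gain was 403 CPM for the markers and 4067 CPM for the interferon list. Single macrophage genes went both ways. Lyz2 rose from 0.0142 to 0.307 CPM and Fcer1g from 1.39 to 3.05, while Apoe fell from 6.31 to 4.39 and Cd68 from 5.38 to 3.97. Genes already high in WT, such as Ighm and Cd74, weigh heavily in the sum, so it would hardly show rare myeloid cells. The gap in gain argues against such cells as the whole source of the response genes, unless their response genes far outweighed their markers. It leaves open whether a few of them made the interferon transcripts. An effect of the deletion on neighbouring genes cannot be told apart from induction. The median log2 fold change of the 6 expressed named genes within 1 Mb of Mir31 that are not interferon genes was 0.0088. Yet among them Cdkn2a (6 counts in WT, 85 in KO) and Cdkn2b (4 and 96) rose, and Mllt3 fell by 0.17. Gene models without a proper name were left out of this median. Of those tested, Gm13283 and Gm13285, both closer to Mir31 than the 6 genes, rose by 2.75 and 1.84 (edgeR adjusted p = 0.0018 and 0.0025). At 149 and 109 kb from Mir31 they lie among the interferon genes, on either side of Ifnz at 127 kb. Their names do not say whether they are interferon genes themselves. Their rise is therefore not taken as that of non-interferon neighbours. Gm26566, Gm26525 and Gm26867 did not pass. The interferon genes of chromosome 7 rose with those of chromosome 4. A response of the cells to the loss of miPEP31 was not tested apart from these explanations.

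The fall of naive and quiescence genes was weighed against 3 technical explanations. Scaling shifts all genes nearly alike, and plain library sizes moved the median of all tested genes only from 0.012 to 0.057. The median of the naive list, -0.48, could therefore not reach 0 in this test, and it was -0.44. The test does not decide on scaling as a cause. It shows only that the list lay below the median of all genes under both scalings. Weaker activation cannot be told apart from the genotype, because early activation genes went both ways (median 0.082, camera adjusted p = 0.987), while 23 G2/M and 14 glycolysis genes were lower. A smaller share of T cells in the KO samples cannot be told apart from the genotype, because 4 T cell identity genes were called higher (2 when any 1 of the WT libraries or KO replicate 2 was left out) while Cd4 and Trac fell, and summed B cell markers overlapped between the groups. The biological explanation, a change of the cells with genotype, stays open beside these as a hypothesis.

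Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the 6806 of the real one, which was the real one itself, and the highest of the others gave 0. For the count of gene lists, 5 of the 10 splits gave at least the 9 lists of the real split, and the highest of the others gave 11. With 10 splits no share under 0.05 is possible in either case. Every other split mixed the genotypes unevenly. Part of the genotype difference thus stayed between its groups and part fell within them, so neither count shows what chance alone gives.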

How the results depend on the processing

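Upper-quartile scaling and plain library sizes for the list tests, libraries left out of the 30-gene table, of the summed interferon genes and of the bounds for Ifna2, Ifit3b, Ifna4 and Ifnl3, and all settings of the seed test except the 8-base match and the transcript choice were added after the data were seen. The count of changed genes, 6806, ranged from 6459 to 6928 over RLE, upper-quartile and plain scaling, the other low-count filters, DESeq2, limma-voom and immune receptor segments left out, and from 5142 to 7233 without 1 library. At adjusted p under 0.01 it was 4367 (2344 higher, 2023 lower), and with a log2 fold change of at least 1 also required it was 1987 (970 higher, 1017 lower), by construction. The balance of directions depended on the scaling: 3266 were higher and 3473 lower with upper-quartile scaling, and 4088 and 2840 with plain library sizes. Nothing in the labels says that the replicate numbers pair the samples. Deviations of same-numbered libraries correlated at 0.0010, -0.0072 and -0.016, which shows no strong shared effect but cannot exclude pairing. A replicate block gave 5736 changed genes, 3049 higher and 2687 lower, and 8 called lists.

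The number of called lists, 9, was 0 with an estimated correlation and 18 with fry, which does not compare a list with other genes; it was 7 to 10 without 1 library. Of 138 named genes past the threshold, 125 kept call and direction in every setting that tested them, the stricter thresholds apart, 13 lost the call in at least 1, and 0 changed sign. A filter of at least 1 CPM in 3 libraries left out 5 of the 138 (Ifna2, Ifit3b, Gata2, Car1 and Pf4), of which 3 are among the 125. Of those not past it, 2 changed sign when 1 library was left out: Ifng ranged from -0.22 to 0.75 and Il17a from -0.83 to 1.22; the cause was not tested. Medians of several uncalled lists changed sign. Without 1 library they ranged from -0.39 to 0.24 (Th2), -0.061 to 0.094 (TGF-beta), -0.051 to 0.0035 (miR-31 targets), -0.064 to 0.19 (co-inhibitory receptors), -0.031 to 0.60 (B cell), -0.051 to 0.49 (plasma cell) and -0.79 to 0.57 (erythroid). Others moved without changing sign: 0.13 to 0.67 (macrophage), 0.18 to 0.63 (dendritic cell), 0.11 to 0.38 (Th1), -0.61 to -0.21 (follicular helper), 0.40 to 0.88 (cytokines), 0.17 to 0.66 (CD8 T and NK cell), 0.028 to 0.27 (Th17), 0.0068 to 0.14 (early activation), -0.18 to -0.0086 (G1/S), 0.0078 to 0.087 (p53), 0.023 to 0.051 (oxidative phosphorylation) and 0.18 to 0.44 (stromal). Members called higher or lower in a list moved by over 1.5 times in 23 counts without 1 library; those not given above were counts of 1 or 2 genes. With a filter of at least 1 CPM in 3 libraries the plasma cell median was -0.0079 and the erythroid median -0.38, from fewer genes. The median of reported miR-31 targets was -0.010 with upper-quartile scaling, and fry called it up at a median of 0.027 (adjusted p = 0.0470); TGF-beta was 0.028 with plain library sizes. The cause was not tested.

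The seed match difference kept its sign and stayed short of the threshold in every setting, from -0.020 with the 8-base match to -0.00012 without WT replicate 3. For the 30 genes of the small table, 29 or 30 were lower without 1 library. A pseudocount of 1 and a filter on low values were not run there, since its values are centred logs. In simulations 44% of genes changed 1.5-fold were recovered. Those simulations gave 176 calls against 6806 here, so the same adjusted p stood for a smaller unadjusted p. That share therefore does not measure what the real comparison missed, although small changes can still be missed.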

Other observations

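The comparison of unnamed loci was chosen after the data were seen. These loci, which carry no gene name, took 0.960% ± 0.0697 of counts in WT and 1.52% ± 0.0703 in KO (SD, n = 3, exact permutation p = 0.1, the smallest possible). All 6 libraries held Xist counts, 40599 or more in WT and 32800 or more in KO, and at most 4.11 counts of Kdm5d, a gene of the Y chromosome.

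Some lists differed among the KO libraries. Relative to the WT mean, the median of the glycolysis list was -0.84, -0.54 and -0.29 in KO replicates 1, 2 and 3 and that of the hypoxia list -1.28, -0.78 and -0.36, whereas the naive list was at -0.61, -0.49 and -0.47 and the regulatory T cell list at 0.39, 0.42 and 0.44. These values are given without a test.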
